A study of Homo sapiens with 4 samples.

How the data were processed

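Total RNA of MCF10A cells was hybridised to 4 Affymetrix U133 Plus 2.0 arrays, 2 from control cells and 2 from the arrays labelled double knockdown of CBL and CBLB. Groups and sample numbers were taken from the sample titles. The deposited values are linear probe set intensities, 1 per probe set and array, as judged from their range. How the authors summarised and normalized these intensities is not given in the sources used here. The 4 arrays had medians of 14.6, 14.6, 14.7 and 14.5 and 95th percentiles of 648, 659, 646 and 664 over all probe sets, so no offset between arrays was visible, and no further normalization was applied. Scanner values were not analysed here.

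The table holds 54675 probe sets. Of these, 62 control probe sets were left out of the gene tests, 41091 named 1 gene in the platform annotation, 1801 named several and 11721 none. Of the probe sets with 1 gene, 41037 were matched by gene identifier to the RefSeq gene table of the GRCh38.p14 assembly, which was used for current symbols only, and the others kept the symbol of the platform annotation. Probe sets that named several genes or none gave no gene name. The probe sets with 1 gene covered 19775 genes. Each gene was represented by its probe set with the highest mean over the 4 arrays. Genes whose mean reached the median of all probe sets, an intensity of 14.6, were tested, which left 12958.

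Values were taken as log2(intensity + 16), a constant fixed beforehand for the case of linear values. Fold changes are on that scale and understate the change of dim genes. Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, two-sided, no covariate, all 4 arrays), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Genes were called at an adjusted p under 0.05. Every adjusted p of a gene in the text is from limma. Standard errors are the moderated ones. Those of single CBL, CBLB and CBLC probe sets come from the same test without the brightness filter, and their p is unadjusted.

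Gene lists were compared with all other tested genes by camera of limma with a preset correlation between genes of 0.01, two-sided, adjusted over 32 lists, and again with the correlation estimated from the data. The calls of the text are those with the preset correlation. With 2 arrays per group, the estimated setting has few degrees of freedom and could hardly call any list. Its p therefore does not decide whether a list shifted. Preranked gene set enrichment, the kind of analysis that the series design names, was run with fgsea 1.28.0 on limma's moderated statistic. Of 955 list entries 847 were matched to a gene with a probe set. The lists covered cytosolic ribosomal proteins, ribosome biogenesis, translation factors, aminoacyl-tRNA synthetases, proteasome subunits, ubiquitin-conjugating enzymes, ER chaperones and the unfolded protein response, ER-associated degradation, ATF4 and CHOP targets, heat shock proteins, chaperonin and prefoldin, autophagy, lysosome, oxidative phosphorylation, ERK output, EGFR ligands and receptor tyrosine kinases, partners of CBL, S phase, G2 and mitosis, p53 targets, NRF2 targets, hypoxia and glycolysis, cholesterol synthesis, interferon-stimulated genes, antigen presentation, NF-kB targets and cytokines, epithelial junctions and keratins, basal cell genes, mesenchymal genes, the cornified envelope, leukocyte markers, and endothelial and fibroblast markers.

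The groups, the design, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule named CBL, CBLB and CBLC, the 12 risen and 12 fallen genes with the largest change among those called with both arrays of each group apart, and up to 4 members of each list with the smallest p. A few members behind a small count were named outside this rule, after their values were seen. Of 122 named genes that were called, 60 had more than 1 probe set above the brightness minimum. CCDC71L, NOP16 and CLDN4 had a probe set of opposite sign, none at an unadjusted p under 0.05. Of the 122, 52 rested on a probe set whose type can match several transcripts.

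The gene test was tested on simulated data for this comparison, with 12958 genes, 200 of them changed. It called 29.9% of genes changed by 0.5 on the log2 scale, 73.1% of those changed by 1 and 90.9% of those changed by 2, and 2.96% of its calls were unchanged genes. Small changes can thus be missed with 2 arrays per group. In the data 15.97% of genes were called, far more than were changed here, so the shares missed need not carry over. A simulated list shifted on purpose had a camera p of 8.45e-25 and an unshifted list 0.901. Simulated genes varied independently, so this does not show how camera treats lists with correlated members.

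Alternatives were array centring, quantile and cyclic loess normalization, the mean of a gene's probe sets, no probe sets that can match several transcripts (suffix _s_at or _x_at), an intensity trend, other constants in the logarithm, other brightness filters, a test against 1.5-fold, every probe set on its own, other list tests, the sample number as a block, and each array left out in turn. A fit that leaves out an array assumes that the lone array of its group varies like the pair of the other. Its error comes from that pair alone, so a call lost without an array need not rest on that array.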

Results

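RNA of MCF10A cells, a human mammary epithelial line that does not form tumours, was measured on 4 Affymetrix U133 Plus 2.0 arrays. The control arrays (n = 2) held cells with a control short hairpin RNA. The arrays labelled double knockdown (n = 2) held cells with hairpins directed at CBL and CBLB, E3 ubiquitin ligases that mark activated receptor tyrosine kinases for degradation. The 1 comparison of the design was therefore between these groups, and the series title names protein homeostasis as its subject. Arrays of the same group correlated across genes at r = 0.995 for the control and 0.997 for the double knockdown, and arrays of different groups at 0.983 to 0.986, where genes are not independent replicates. The number of arrays limited the precision of every value. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

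The first question was whether the targeted transcripts were lower. CBL fell 2.59-fold, from an intensity of 105 ± 29.3 (SD, n = 2) in the control to 30.1 ± 1.53 (n = 2) on its brightest probe set (log2 change -1.37 ± 0.15 SE, adjusted p = 0.00137 by limma). The control arrays read 125.9 and 84.4 and the double knockdown arrays 31.1 and 29.0. CBLB was not lower. Its brightest probe set rose 1.36-fold, from 67.2 ± 4.09 to 97.2 ± 3.30 (log2 change 0.45 ± 0.09 SE, adjusted p = 0.0147), with 64.3 and 70.05 in the control and 94.8 and 99.5 in the double knockdown. CBLC, the remaining member of the family, rose 1.37-fold on its brightest probe set (log2 change 0.45 ± 0.09 SE, adjusted p = 0.0161), while its other probe set had a log2 change of 0.03 with an unadjusted p of 0.822. The transcript of CBLB thus went against its label, and the arrays are called "labelled double knockdown" here for that reason. Each direction below is that of these arrays against the control arrays.

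The other probe sets moved less. Of the other 4 probe sets of CBL, the brightest had a log2 change of -0.33 with an unadjusted p of 0.0325 and the next of -0.20 with 0.0534. The remaining pair lay below the brightness minimum, at -0.05 with 0.306 and -0.12 with 0.0658. For CBLB, the second probe set had a log2 change of 0.40 with an unadjusted p of 0.0449, and the third, below the brightness minimum, of -0.02 with 0.676. With the mean of a gene's probe sets in place of the brightest, the log2 change of CBL was -0.41, with adjusted p = 0.0154. The call of CBLB was lost without double knockdown replicate 1 (adjusted p = 0.0886) and without double knockdown replicate 2 (adjusted p = 0.141), and that of CBLC without control replicate 1 (0.0518), double knockdown replicate 1 (0.113) or double knockdown replicate 2 (0.129).

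**Figure D1:**
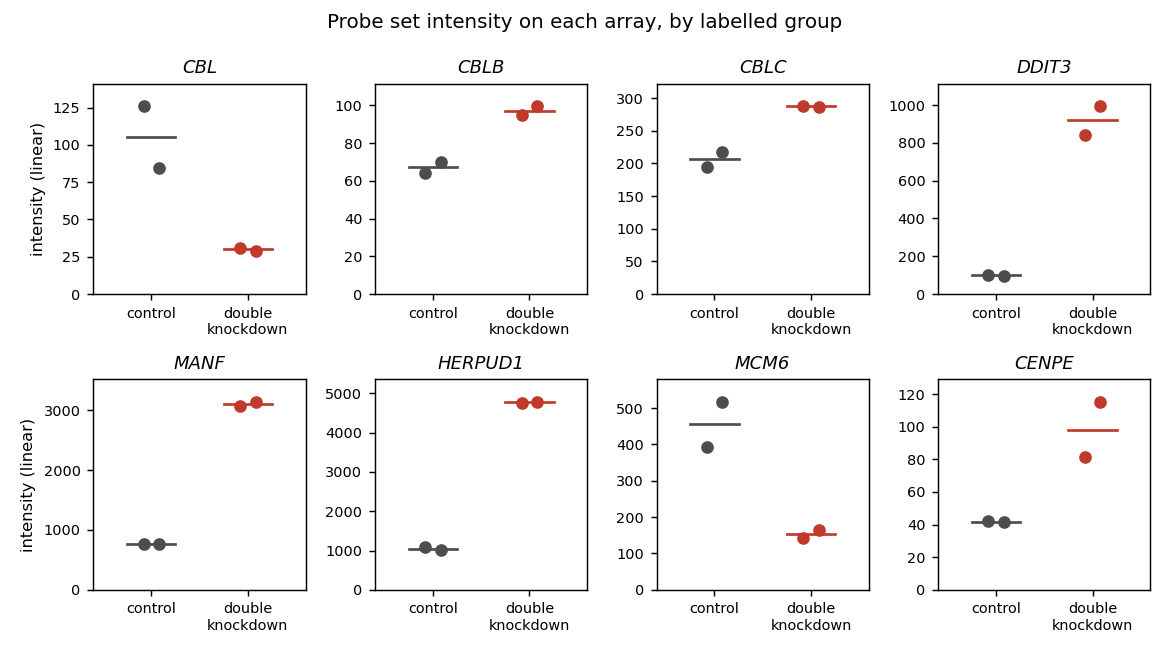
Intensity (linear scale) of the brightest probe set of 8 genes on each array, with control arrays in grey, arrays labelled double knockdown in red, 1 point per array and a bar at the mean of the group. CBL lies at 31.1 and 29.0 on the double knockdown arrays against 125.9 and 84.4 on the control arrays, while CBLB lies higher, at 94.8 and 99.5 against 64.3 and 70.05.

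The next question was which transcripts differed. On the log2(intensity + 16) scale, the highest rise was that of AKAP12, a scaffold protein that binds protein kinase A, from an intensity of 20.01 ± 0.0356 (SD, n = 2) to 288 (8.44-fold, log2 change 3.08 ± 0.08 SE). DDIT3, which encodes the stress transcription factor CHOP, followed on that scale with an 8.14-fold rise from 98.4 ± 1.02 to 918 ± 107 (log2 change 3.02 ± 0.10 SE). Genes of endoplasmic reticulum (ER) function held many of the next places: ERO1B, an ER oxidase, rose 5.69-fold, the disulfide isomerase AGR2 5.63-fold, the chaperone cofactors SDF2L1 and DNAJB9 5.55-fold and 4.90-fold, and HERPUD1, which acts in the degradation of ER proteins, 4.49-fold. HMOX1, which breaks down heme, rose 5.79-fold, NIBAN1 5.11-fold, ZNF165 5.04-fold, CCDC71L 4.31-fold and CD14, a receptor for lipopolysaccharide, 4.23-fold. The adjusted p of these 12 genes lay between 7.11e-06 for AKAP12 and 8.22e-05 for ZNF165.

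The largest fall on that scale was that of GJA1, the gap junction protein connexin 43, from 126 ± 3.17 (SD, n = 2) to 19.2 (4.04-fold, log2 change -2.01 ± 0.09 SE, adjusted p = 2.31e-05). Keratinocyte genes were among the others: PI3, the protease inhibitor elafin, fell 3.56-fold, KRT16 3.27-fold, KRT14, a keratin of basal cells, 3.07-fold, and SPRR2B, a component of the cornified envelope, 2.95-fold. THBS1, a matrix glycoprotein, fell 3.72-fold, the intermediate filament gene VIM 3.39-fold, the FGF carrier FGFBP1 3.30-fold, TXNIP, an inhibitor of thioredoxin, 2.98-fold, FLRT3 2.97-fold, ZNF738 2.96-fold and TFCP2L1 2.86-fold. THBS1 had the widest error of the 12 (log2 change -1.89 ± 0.23 SE, adjusted p = 0.00197).

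Of 12958 genes tested, 2070 (15.97%) differed at an adjusted p under 0.05, 1216 of them higher and 854 lower on the arrays labelled double knockdown. The median size of a called change was 0.48 on the log2 scale, and 124 genes were higher and 38 lower by at least 2-fold. For each gene that the naming rule chose and that passed the test, both arrays of one group lay beyond both arrays of the other. For the 12 risen and 12 fallen genes this was a condition of the rule. For the others a call with 2 arrays per group makes it likely, so it is no further support. Fits without 1 array do not show whether the count rested on that array. Without a double knockdown array, the error came from the control pair alone. That pair had a median absolute log2 difference of 0.115, against 0.0877 for the double knockdown pair. Folds are of intensity + 16 and understate the change of dim genes: without that constant, the fold was 14.4 for AKAP12, 9.31 for HMOX1, 8.21 for NIBAN1, 6.59 for GJA1 and 3.89 for SPRR3. The order of genes by fold depends on the constant, and for ERO1B, IL24 and KRT23 in the control and ZNF738 in the double knockdown the mean lay below the brightness minimum, so no fold without it is given.

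**Figure D2:**
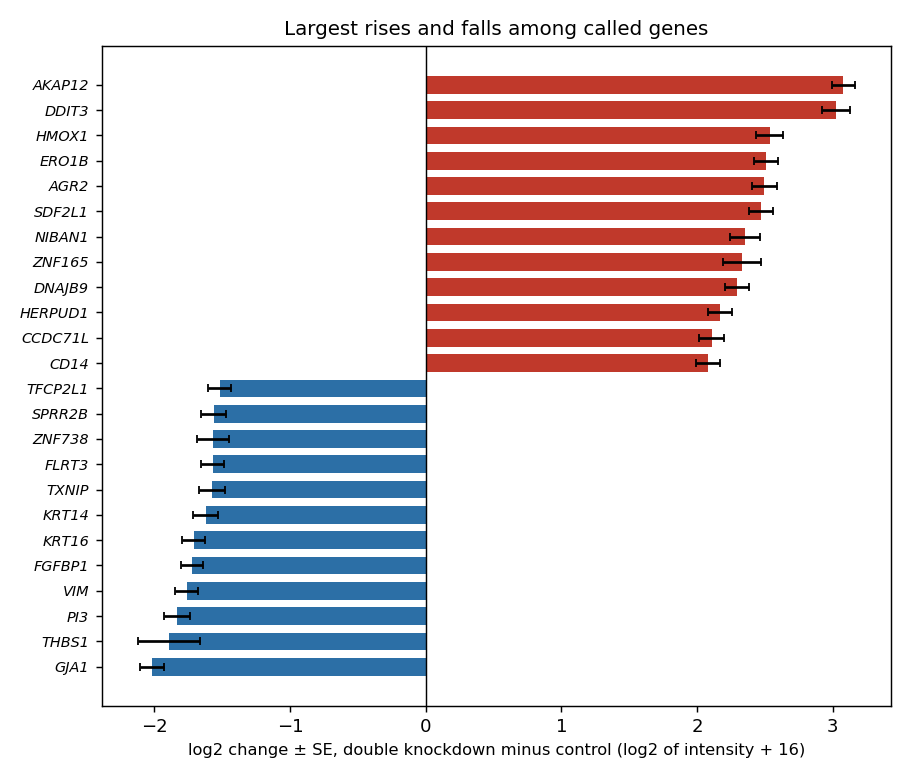
Log2 change (arrays labelled double knockdown minus control, log2 of intensity + 16) of the 12 genes with the largest rise (red) and the 12 with the largest fall (blue) among those that passed the test, with bars for the standard error. Rises reach 3.08 for AKAP12 and falls -2.01 for GJA1.

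Gene lists for protein synthesis, folding and breakdown, for signalling, for epithelial state and for other cell types were then compared with all other genes by limma's camera. ER chaperones and other genes of the unfolded protein response showed the largest shift. Of 26 tested members 16 rose and none fell (18 and 0 adjusted over the list alone), with a median log2 change of 0.90 and an adjusted p of 9.71e-15. With an estimated correlation the list had adjusted p = 0.432. ERO1B, SDF2L1 and DNAJB9 rose as given above, and MANF, a secreted ER stress protein, rose 4.01-fold (log2 change 2.01 ± 0.08 SE). Named after their values were seen, HSPA5, the main ER chaperone BiP, rose 3.78-fold and XBP1, a transcription factor of the response, 2.03-fold.

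Genes of ER-associated degradation, which returns misfolded proteins to the cytosol, were higher as a list (adjusted p = 0.0172, and adjusted p = 0.621 with an estimated correlation, median log2 change 0.10). Of 20 tested, 7 rose and 3 fell (9 and 3 adjusted over the list alone). HERPUD1 rose 4.49-fold, SEL1L, a subunit of the ubiquitin ligase complex of the ER membrane, 2.85-fold (log2 change 1.51 ± 0.09 SE), DERL2 2.79-fold and SELENOS 1.95-fold. The members that fell were VCP (log2 change -0.34), UFD1 (-0.48) and STUB1 (-0.33), which act in the cytosol. Without control replicate 2 the list had a median of 0.03 and adjusted p = 0.0645, and without control replicate 1 a median of 0.15.

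Targets of ATF4 and CHOP, transcription factors of the integrated stress response, were higher (adjusted p = 2.35e-05, median log2 change 0.30), with 12 members up and 1 down of 27 (14 and 2 adjusted over the list alone). With an estimated correlation the list had adjusted p = 0.662. DDIT3 rose as above, the cystine transporter SLC7A11 rose 2.46-fold (log2 change 1.30 ± 0.10 SE), CHAC1, which degrades glutathione, 2.07-fold, and SESN2 1.91-fold. The member that fell was ASNS, asparagine synthetase (log2 change -0.65 ± 0.08 SE, adjusted p = 0.00273).

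**Figure D3:**
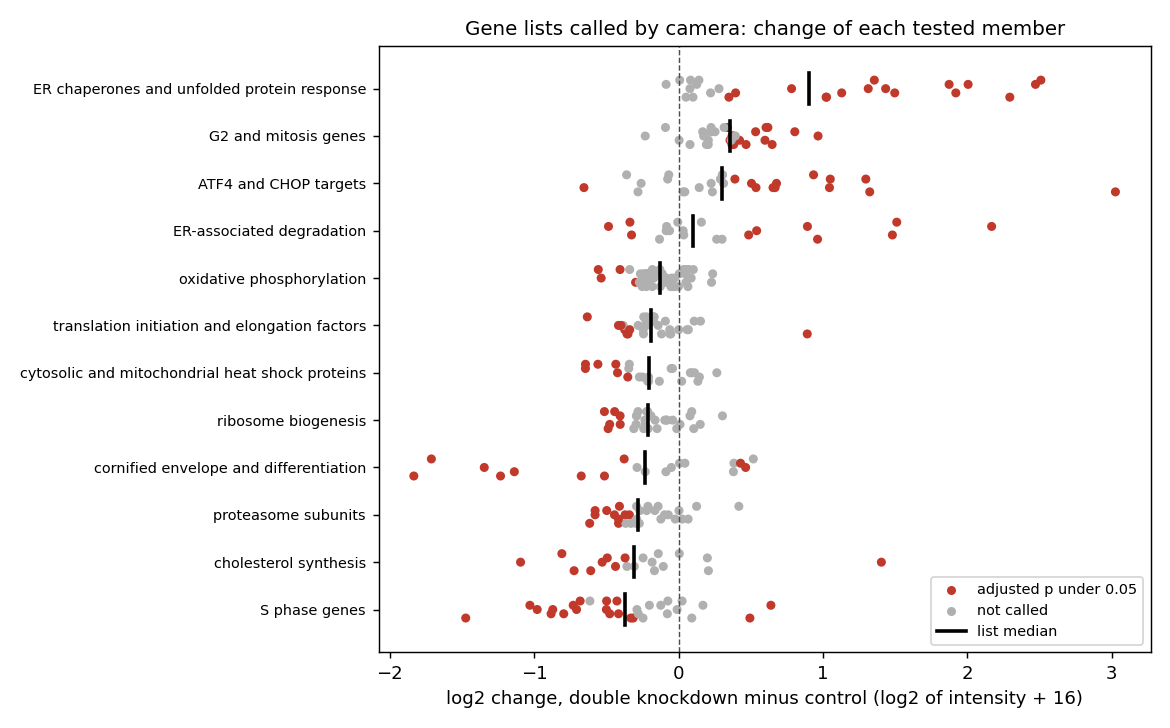
Log2 change (arrays labelled double knockdown minus control, log2 of intensity + 16) of each tested member of the 12 gene lists called by camera, with members at an adjusted p under 0.05 in red, the others in grey and a black bar at the median of the list. Medians run from 0.90 for ER chaperones and the unfolded protein response to -0.37 for S phase genes.

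Proteasome subunits were lower (adjusted p = 1.05e-05, median log2 change -0.28), with 10 of 30 down and none up (17 and 1 adjusted over the list alone). The list had adjusted p = 0.74 with an estimated correlation. PSMD3 fell by 1.53-fold, PSMD14 and PSMC3 by 1.49-fold each and PSMC4 by 1.41-fold. Cytosolic and mitochondrial heat shock proteins were lower (adjusted p = 0.00596, median log2 change -0.21), with 6 of 23 down and none up (8 and 0 adjusted over the list alone). The heat shock list had adjusted p = 0.662 with an estimated correlation and 0.0685 without control replicate 2. CRYAB and the cochaperone DNAJA1 each fell 1.56-fold, HSPH1 1.47-fold and FKBP4 1.35-fold. Among these named genes, CRYAB kept its call whichever array was left out. PSMC3 (0.0857) and DNAJA1 (0.0628) lost theirs without double knockdown replicate 1, PSMD3 (0.0612) and PSMD14 (0.0718) without double knockdown replicate 2, and PSMC4 (up to 0.124), HSPH1 (up to 0.0689) and FKBP4 (up to 0.144) when either was left out.

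Ribosome biogenesis genes were lower (adjusted p = 0.000427, median log2 change -0.21), with 6 of 31 down and none up (11 and 0 adjusted over the list alone). With an estimated correlation they had adjusted p = 0.662. LYAR fell 1.40-fold, NIP7 1.36-fold, NOP16 1.43-fold and MRTO4 1.39-fold, and each lost its call without double knockdown replicate 1 or 2, with adjusted p up to 0.126. Translation initiation and elongation factors were lower too (adjusted p = 0.000427, median log2 change -0.19), with 7 of 34 down and 1 up (7 and 1 adjusted over the list alone). These factors had adjusted p = 0.432 with an estimated correlation. EIF1AX fell 1.55-fold, EIF5B 1.32-fold and EIF3K 1.33-fold, while EIF5, which promotes GTP hydrolysis by EIF2, rose 1.85-fold. Without probe sets that can match several transcripts, the factor list had adjusted p = 0.165 and EIF5 0.782. That setting also took the calls of EIF5B (log2 change -0.11, adjusted p = 0.545) and MRTO4 (-0.31, 0.0901). EIF1AX lost its call without double knockdown replicate 2 (0.0643), EIF5B whichever array was left out (up to 0.218) and EIF3K when control replicate 1 or either double knockdown array was left out (up to 0.23). None of the 51 cytosolic ribosomal proteins tested passed the test over all genes or over the list alone, at a median log2 change of 0.01 and an adjusted p of 0.702 with camera's direction down. RPL6, RPL14, RPL35 and RPL19, with the smallest p, had log2 changes of -0.17, -0.18, -0.16 and -0.14.

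Cell cycle genes divided by phase. S phase genes were lower (adjusted p = 1.76e-07, median log2 change -0.37), with 16 of 30 down and 2 up (20 and 2 adjusted over the list alone). With an estimated correlation the S phase list had adjusted p = 0.662. MCM6, a subunit of the replicative helicase, fell from 455 ± 87.7 (SD, n = 2) to 153 ± 15.3, or 2.78-fold, UHRF1 fell 2.04-fold, the polymerase clamp PCNA 1.83-fold and MCM2 1.73-fold. The members that rose were RRM2 (log2 change 0.49) and CDC6 (0.64). Genes of G2 and mitosis were higher (adjusted p = 1.44e-08, median log2 change 0.36), with 15 of 31 up and none down (19 and 0 adjusted over the list alone). The G2 and mitosis list had adjusted p = 0.432 with an estimated correlation. The kinetochore motor CENPE rose 1.95-fold, CENPF 1.75-fold, UBE2C 1.57-fold and the checkpoint kinase BUB1 1.52-fold. BUB1, at a log2 change of 0.61, lost its call without double knockdown replicate 2 (log2 change 0.54). It also lost it with the mean of a gene's probe sets (log2 change 0.21, adjusted p = 0.0781).

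Cholesterol synthesis genes were lower (adjusted p = 0.000587, median log2 change -0.31), with 8 of 19 down and 1 up (9 and 1 adjusted over the list alone). The list had adjusted p = 0.432 with an estimated correlation and 0.063 by preranked gene set enrichment. INSIG1 fell 2.13-fold, HMGCS1 1.75-fold and the epoxidase SQLE 1.65-fold, while STARD4, a sterol carrier, rose 2.65-fold. SQLE had adjusted p = 0.0513 without double knockdown replicate 2. Genes of oxidative phosphorylation were lower by a small amount (adjusted p = 0.00169, median log2 change -0.13), with 4 of 50 down and none up (3 and 0 adjusted over the list alone): NDUFA9 fell 1.47-fold, UQCRC1 1.45-fold, ATP5MC1 1.32-fold and ATP5F1B 1.23-fold. That list had adjusted p = 0.809 with an estimated correlation and, without control replicate 2, adjusted p = 0.0829 at a median of -0.08. UQCRC1 lost its call without double knockdown replicate 1 (0.0865), NDUFA9 when either double knockdown array was left out (up to 0.0618), ATP5MC1 without these or control replicate 2 (up to 0.208) and ATP5F1B whichever array was left out (up to 0.264).

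Genes of the cornified envelope, the protein coat of differentiated keratinocytes, were lower (adjusted p = 0.00523, median log2 change -0.23), with 8 of 19 down and 2 up (10 and 4 adjusted over the list alone). This list had adjusted p = 0.676 with an estimated correlation, 0.0829 without control replicate 2 and 0.119 with the stricter brightness filter. Its median was -0.07 without control replicate 2, -0.15 without control replicate 1 and -0.05 with that filter. KRT16 and PI3 fell as above, SPRR3 fell 2.54-fold (3.89-fold without the constant) and SPRR1B 2.20-fold, while TGM1 (log2 change 0.43) and S100A7 (0.46) rose. Lists of epithelial junctions and keratins (adjusted p = 0.109), basal cell genes (0.342) and mesenchymal genes (0.467) were not called by camera. Preranked gene set enrichment called the junction and keratin list higher (adjusted p = 0.0355), which had adjusted p = 0.748 by camera with an estimated correlation. Among 29 junction and keratin genes 10 rose and 4 fell (11 and 6 adjusted over the list alone). ELF3, an epithelial transcription factor, rose 2.99-fold, KRT23 2.29-fold from a control mean of 14.03, below the brightness minimum, the tight junction protein OCLN 1.71-fold and CLDN4 1.61-fold. Of 16 basal cell genes 3 rose and 4 fell (3 and 4 adjusted over the list alone). KRT14 and KRT5 (1.66-fold) were down, and LAMB3 (2.12-fold) and MYLK (1.81-fold) were up. LAMB3 had adjusted p = 0.0507 without a brightness filter. Of 15 mesenchymal genes LOX rose 2.60-fold while VIM and FN1 (2.43-fold) fell (1 and 3 adjusted over the list alone).

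Signalling lists close to the known action of CBL proteins were not called. Of 23 genes of ERK output and feedback 3 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.702). DUSP5 rose 1.47-fold, PHLDA1 1.82-fold and TRIB1 1.65-fold, and CCND1, which encodes cyclin D1, fell 2.02-fold. Of 15 EGFR ligands and receptor tyrosine kinases 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.316). EREG rose 1.92-fold, HBEGF 1.55-fold and MET 1.24-fold, and FGFR3 fell 1.54-fold. Without control replicate 1 both lists were called higher, at adjusted p = 0.00323 for ERK output and 0.00506 for the ligands and receptors. With an estimated correlation over all arrays they had adjusted p = 0.924 and adjusted p = 0.809. The median log2 change of ERK output was 0.06 with all arrays, 0.27 without control replicate 1 and -0.17 without control replicate 2, and that of the ligands and receptors 0.13, 0.30 and 0.04. Without control replicate 2 the log2 change was 0.51 in place of 0.87 for PHLDA1, 0.41 in place of 0.72 for TRIB1 and 0.34 in place of 0.63 for HBEGF, and without control replicate 1 it was -0.40 in place of -0.62 for FGFR3. Of 25 partners of CBL in receptor down-regulation 3 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.677): the adaptor SH3KBP1 rose 1.57-fold, CBLC 1.37-fold and CRKL 1.28-fold, and PIK3R1 fell 1.54-fold. With the mean of a gene's probe sets, TRIB1 (log2 change 0.25), FGFR3 (-0.28), HBEGF (0.35), MET (0.19), CRKL (0.21) and CBLC (0.24) were not called. PHLDA1, TRIB1 and HBEGF also lost their calls with a constant of 1 or 64 or with none (adjusted p up to 0.0796). Without a brightness filter these genes had adjusted p = 0.126, 0.13 and 0.149. CCND1 (0.0604), FGFR3 (0.0878) and MET (0.0535) lost their calls in that setting too. Of the genes in this paragraph, EREG and SH3KBP1 kept their calls whichever array was left out. DUSP5 (0.0843), CCND1 (0.0749) and PIK3R1 (0.0567) lost theirs without double knockdown replicate 2, PHLDA1 (up to 0.141), TRIB1 (up to 0.147) and FGFR3 (up to 0.133) when either double knockdown array was left out, HBEGF (up to 0.18) also without control replicate 2, CBLC (up to 0.129) also without control replicate 1, and MET (up to 0.274) and CRKL (up to 0.249) whichever array was left out.

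Other lists of protein turnover were not called. Of 17 aminoacyl-tRNA synthetases 2 rose and none fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.467): WARS1 rose 1.61-fold and AARS1 1.26-fold. Of 25 ubiquitin-conjugating and activating enzymes 3 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.721): UBE2J1, an enzyme of the ER membrane, rose 1.58-fold and UBA1, the main activating enzyme, fell 1.62-fold. Of 12 chaperonin and prefoldin subunits PFDN2 rose 1.42-fold and VBP1 fell 1.35-fold (1 and 4 adjusted over the list alone, camera adjusted p = 0.316). Of 33 autophagy genes 5 rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.519), with WIPI1 up 2.73-fold and ATG3 down 1.55-fold. Of 32 lysosome genes NPC1, a cholesterol exporter, rose 2.05-fold and CTSB 1.29-fold, and none fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.702). UBE2J1 lost its call without double knockdown replicate 2 (0.0597), UBA1 (up to 0.101), PFDN2 (up to 0.122) and VBP1 (up to 0.123) when either double knockdown array was left out, CTSB without these or control replicate 2 (up to 0.206), and AARS1 whichever array was left out (up to 0.244).

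Camera did not call NRF2 targets, p53 targets, hypoxia and glycolysis genes or the 3 immune lists. Preranked gene set enrichment called NRF2 targets (adjusted p = 0.00361) and antigen presentation (0.0376) higher. With an estimated correlation camera gave adjusted p = 0.759 for NRF2 targets, 0.662 for antigen presentation and 0.809 for NF-kB targets. Of 21 NRF2 targets 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.112): HMOX1 rose as above, GCLM, for glutathione synthesis, 1.79-fold and AKR1C1 1.61-fold, and AKR1B10 fell (log2 change -0.61). Without probe sets that can match several transcripts this list was called higher, at adjusted p = 0.00538. Of 21 p53 targets GDF15 rose 3.79-fold and TP53I3 (1.42-fold) and SESN1 (1.37-fold) fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.702). Of 27 hypoxia and glycolysis genes 6 rose and 3 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.524), with VEGFA up 2.42-fold, ANKRD37 2.11-fold and P4HA1 1.85-fold. Of 30 interferon-stimulated genes 7 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.342), with IFITM1 up 2.54-fold and IFI27 1.98-fold and OAS1 down (log2 change -0.58). Of 17 antigen presentation genes HLA-DMA rose 1.37-fold and none fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.102). Without a brightness filter that list was called higher, at adjusted p = 0.0211. Of 22 NF-kB targets and cytokines 6 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.342). LCN2 rose 3.03-fold, IL24 2.73-fold from a control mean of 10.6, below the brightness minimum, IL1B 2.20-fold and CCL20 1.94-fold, while CXCL1 (log2 change -0.87), CXCL2 (-0.68) and TNFAIP3 (-0.52) fell. Without probe sets that can match several transcripts the NF-kB list was called higher, at adjusted p = 0.0406. TP53I3 (up to 0.0968), SESN1 (up to 0.126) and OAS1 (up to 0.102) lost their calls when either double knockdown array was left out, and HLA-DMA without these or control replicate 1 (up to 0.228).

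Camera called neither list of markers of cell types other than epithelium. Of 9 leukocyte markers tested, CD14 rose 4.23-fold, CORO1A rose 1.73-fold and ITGB2 fell 1.42-fold (2 and 1 adjusted over the list alone, camera adjusted p = 0.387). The leukocyte list was called higher by fry (adjusted p = 0.0453) and by preranked gene set enrichment (0.0177), at a median log2 change of 0.02 and an adjusted p of 0.809 by camera with an estimated correlation. Of 5 endothelial and fibroblast markers tested, DCN fell 1.76-fold and none rose (0 and 1 adjusted over the list alone, camera adjusted p = 0.387). CORO1A lost its call without double knockdown replicate 2 (adjusted p = 0.06) and ITGB2 when control replicate 1 or either double knockdown array was left out (up to 0.177). The 3' over 5' signal ratio of GAPDH, a sign of RNA integrity, was 1.091 and 1.071 in the control and 1.105 and 1.082 in the double knockdown, which overlap. That of ACTB was higher on both double knockdown arrays, at 1.683 and 1.617 against 1.616 and 1.568.

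In all, 12 of 32 lists were called, 4 higher and 8 lower. None held with an estimated correlation, where the smallest adjusted p was 0.432. That setting takes its p from the residual degrees of freedom, which are few with 2 arrays per group. Even the ER chaperone list, at an unadjusted camera p of 3.03e-16 with the preset correlation, had 0.0278 there. The setting could thus hardly call any list, and a call lost in it counts neither for nor against a list. The few degrees of freedom raised p also where the estimated correlation was no higher than the preset one. For translation factors, cholesterol synthesis and ER-associated degradation the estimate was -0.00382, -0.0209 and -0.0269, below the preset 0.01. Their unadjusted camera p still rose, from 9.34e-05 to 0.0459, from 0.000147 to 0.054 and from 0.00644 to 0.097. A call lost in this setting therefore does not show that the members were correlated. The rotation test fry, which asks whether a list's genes move on balance in 1 direction, called 5 lists (smallest adjusted p = 0.0332), including 4 of the 12. Preranked gene set enrichment called 15, including 11 of the 12. It ranked genes by the same limma statistic and takes no account of correlation between members. Its calls are thus not independent of those of camera. The median and the direction of the test differed in sign for cytosolic ribosomal proteins and for ubiquitin-conjugating enzymes, and the p53 list had a median log2 change of -0.05 and a mean of 0.04.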

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

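The tests of array offset, exchanged labels, the second CBLB probe set and the share of dividing cells were chosen after the results were seen. Probe sets that name no single gene took no part in the comparison of genes. Among 4380 of them above the brightness minimum, limma called 359 higher and 193 lower on the arrays labelled double knockdown (12.6%). None of the 62 control probe sets was called, with 0 at an unadjusted p under 0.05 as well. The control probe sets were fitted and adjusted apart from the others, so these counts are not a like comparison.

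The rise of CBLB on arrays labelled as its knockdown calls for a check of the labels. An exchange of the groups' labels would have put CBL higher on these arrays, but its log2 change was -1.37. A single misbehaving probe set is argued against by the other CBLB probe set above the brightness minimum, whose log2 change was 0.40 with an unadjusted p of 0.0449. That probe set is dim, and the call of CBLB itself was lost without double knockdown replicate 1 (adjusted p = 0.0886) or 2 (0.141). What stays open includes a hairpin that acts on protein more than on transcript, a response of the CBLB gene to the loss of CBL, and arrays of cells without an effective CBLB hairpin. None of these was tested, and array values of RNA do not measure the proteins.

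The rise of ER chaperones and unfolded protein response genes could come from an offset between arrays or from the brightness of the probe sets. The median log2 change of all tested genes was -0.0085, against a lower quartile of 0.13 for the list, which argues against an offset. The list's median lay at percentile 100 of 10000 random lists matched on brightness. A biological difference between the groups may account for the rise, as a hypothesis found and tested on the same arrays. Which hairpin or protein it follows from was not tested.

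A fall of S phase genes beside a rise of G2 and mitosis genes could come from a smaller share of dividing cells. That alone would have lowered both lists, and the median log2 change of the G2 and mitosis list was 0.36. This value is part of the pattern itself, so it argues only against a smaller share as the whole cause, and a smaller share beside another change stays open. The distance between the medians of both lists lay at percentile 100 of 10000 random pairs of lists matched on brightness. This bears only on brightness. On their own the S phase list lay at percentile 0 and the G2 and mitosis list at 100 of matched random lists. The pair was picked for these opposite shifts, so their distance adds no further support. A difference in the share of cells in each phase may account for it, as a hypothesis.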

How the results depend on the processing

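The setting with no constant in the logarithm was chosen after the data were seen. No called result reversed direction. CBL kept its call in all settings that gave it a value (log2 change -0.41 to -1.78). Without a brightness filter, 12 other genes chosen by the naming rule lost their calls. Among them were UBA1 (adjusted p = 0.0703), EIF3K (0.0635), HLA-DMA (0.093) and ITGB2 (0.08). With no constant, 568 genes were lower. Against a change of 1.5-fold, 121 genes were called (95 higher, 26 lower), and with every probe set on its own 3430 probe sets (1917 higher, 1513 lower). Other settings of scaling, probe sets, prior, constant and filter called 1475 to 2186 genes, of which 1398 to 2070 were shared with the genes reported. Leaving out 1 array gave 454 to 2061 genes (326 to 1165 higher, 128 to 896 lower), with 454 without double knockdown replicate 2 and 655 without double knockdown replicate 1. CBLB then ranged from 0.40 to 0.50, with adjusted p = 0.141 and 0.0886 without these arrays, over a range of 0.012 to 0.141 in all settings. Lists called ranged from 8 to 14 (3 to 6 higher, 5 to 8 lower). Camera with an estimated correlation called 0 lists (0 higher, 0 lower), fry 5 (1 lower) and preranked enrichment 8 higher. Fewer arrays leave fewer degrees of freedom, and without a double knockdown array the error comes only from the more variable control pair. Camera with an estimated correlation is limited by its few degrees of freedom too. The cause of the remaining differences was not tested. With the replicate block, 2520 genes were called, 2050 of them among the 2070. The numbers are not known to pair the arrays: with 2 pairs, the differences between sample 2 and sample 1 in both groups correlated at 0.244 across genes. Dim probe sets limit what can be seen: among genes below the brightness minimum, a change is compressed by the constant.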

Other observations

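The lists in this part were drawn up after the gene results were seen but before their own tests were run, and the grouping of ATF4 and CHOP targets and its test were chosen after its members' values were seen. Genes of ER transport and processing outside the earlier lists were higher with the chaperones. A list of COPII vesicles and transport between the ER and the Golgi also held COPI coat subunits and KDEL receptors. Of its 34 tested genes 8 rose and 1 fell (camera adjusted p = 0.00853 over 6 added lists, and adjusted p = 0.61 with an estimated correlation). Among them were the coat subunit SEC24D (log2 change 0.87 ± 0.17 SE), BET1 (0.86 ± 0.10) and the cargo receptor LMAN1 (0.67 ± 0.09), with ERGIC1 lower (-0.74 ± 0.09). Of 31 N-glycosylation genes 7 rose and none fell (camera adjusted p = 0.00853, and 0.61 with an estimated correlation), led by GFPT1, the entry enzyme of the hexosamine pathway (1.13 ± 0.11), OSTC (0.71 ± 0.10) and the oligosaccharyltransferase subunit RPN1 (0.56 ± 0.08). Of 19 genes of ER translocation and signal peptidase 5 rose and none fell (camera adjusted p = 0.00853, and 0.652 with an estimated correlation), with SPCS2 (0.74 ± 0.10), SPCS3 (0.72 ± 0.11) and TRAM1 (0.70 ± 0.09). Of the translocation genes placed in the earlier ER list, SEC61A1, SEC61B, SSR1, SRP72 and SERP1 were not called, at log2 changes of 0.14, 0.05, 0.13, 0.08 and 0.22. Since the lists were chosen after the rise of the chaperones was seen, their p is not independent evidence of a shared rise.

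Other additions did not give a call. ID1 rose 3.98-fold, but other targets of BMP and SMAD signalling did not rise as a list (1 higher, 1 lower of 9, camera adjusted p = 0.658). THBS1 fell, while targets of YAP and TEAD had 3 members higher and 2 lower of 19 (camera adjusted p = 0.479). AGR2 and ELF3 rose, while luminal and secretory epithelial genes had 0 higher and 1 lower of 10 (camera adjusted p = 0.639). A missed call does not show that they did not shift.

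ATF4 and CHOP targets may divide by function. The 10 tested members that are enzymes of amino acid, one-carbon and related metabolism had a median log2 change of -0.07, with 1 called higher (MTHFD2) and 1 lower (ASNS). The other 17, which include CHAC1, the enzyme that degrades glutathione, had a median of 0.65, with 11 called higher. The difference had a permutation p of 0.00054 (two-sided, 1e+05 resamples). The grouping was made with the values known and members of a list are not independent, so the p does not decide whether the division would hold in other samples.

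Only 3 splits of the 4 arrays into 2 and 2 exist, too few for a share under 0.05. The real split called 2070 genes with limma, and the highest of the others 0. At an unadjusted p under 0.05 by limma, the others had 108 and 14 genes against 3958. Both groups of each other split held a control array and a double knockdown array. Any difference between control and double knockdown thus went into the error of these splits, which by itself lowers their counts. They cannot show how many genes would be called without a difference, so no conclusion is drawn from them.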
